A study of Arabidopsis thaliana with 4 samples.

How the data were processed

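RNA was sequenced from whole Arabidopsis thaliana plants of 2 genotypes, wild type (WT) and a line that overexpresses the transcription factor gene TEM1, named 35S:TEM1 after the strong plant promoter of cauliflower mosaic virus. There were 2 samples per genotype and 4 in all. Each sample was a pool of 20 plants, 10 days old, grown at 22 °C in LD and harvested at ZT18, per the labels. Total RNA was treated with DNase before libraries were made, per the labels' protocols. The labels give no batch, sequencing date or independent growth round, so p-values measure only the spread between these pooled samples.

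The deposited table holds 1 RPKM value (reads per kilobase of gene, scaled to the reads of the library) for each of 32678 loci and each sample, and its columns are named for the samples. All of its value columns belong to these 4 samples. The submitters' processing notes name bcl2fastq 1.8.4, FastQC, STAR and Cuffdiff 2.2.1 and the TAIR10 build, with no role or order. The counting tool, the gene annotation, the strand setting and the filters on reads are not given in the sources used here. Which of these tools made the RPKM values of the authors is likewise not given.

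Gene names, gene types and neighbours came from the RefSeq annotation of the TAIR10.1 assembly, which held 31912 of the 32678 loci (97.7%). Because the builds differ in name, no coordinates from it are printed. Loci are given with their chromosome number, which is part of each locus identifier.

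The low values carry the depth. Relative depth came from the most frequent ratio between samples among low genes, and the total from the smallest values of 1213 loci, which gave the same scaling total, within 5000 reads, when taken as 1 read over the reference exon length. The totals were 20.18 M reads (M, units of 1e+06) for 35S:TEM1 replicate 1, 27.81 M for 35S:TEM1 replicate 2, 30.43 M for WT replicate 1 and 24.14 M for WT replicate 2. In a gene of 1 kb, 3 reads correspond to an RPKM of 0.149, 0.108, 0.099 and 0.124 in the same order, a floor that covers counting error only. With reference exon lengths, 31.3% to 33.5% of values under 50 reads came out whole within 0.05 of a read, against 10% by chance. The reads recovered with these lengths also summed to 1.17 times the totals in each sample. The read numbers are therefore estimates, and a test on them served only as an alternative.

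Without a stated strand setting, it is not known whether reads of genes that overlap on opposite strands were told apart. Overlaps noted beside genes in the results compare whole gene spans, introns included, and need not involve exons. Among protein-coding genes with no exon overlap on their own strand, those with at least 90% of their exon length under a listed gene of the opposite strand had a median RPKM of 0.545 (293 genes), and 58.0% of them lay under an RPKM of 1. With 50% to 90% overlapped the median was 0.519 (249 genes, 57.0% under 1), with less than 50% it was 8.69 (5002 genes, 18.4% under 1), and with no overlap at all it was 3.27 (20215 genes, 39.0% under 1), so the level does not fall steadily with overlap. F3H, SPL3, SPL15 and MYC2 are list members with an overlap of at least 90%, and their levels are uncertain. Reads shared between closely related copies are also uncertain. This may concern LHCB1 and LHCB2 genes, AOC1 and AOC2, VSP1 and VSP2, TGG1 and TGG2, BHLH38 and BHLH39, and AT1G67860 and AT1G67865. No sequences were compared to check this.

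Values were analysed as log2(RPKM + 1), and fold changes are 35S:TEM1 minus WT on that scale, which understates the change of genes with low values. Genes with a mean RPKM over the 4 samples of at least 1 were tested (17746 genes), using limma 3.58.1 in R 4.3.3 with a mean-variance trend, 2-sided, and Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 are called higher or lower. The moderated variance had 2 residual and 4.17 prior degrees of freedom. The errors of log2 values are standard errors (SE) from limma, and those of RPKM values are standard deviations (SD).

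In simulated data with the genes and moderated spread of this comparison, 98 of 100 genes changed by 1 on the log2(RPKM + 1) scale were recovered. Of those changed by 2 on that scale, 100 of 100 were recovered, with 20 false calls among 17746 genes. In genes with low values such shifts exceed a 2-fold or 4-fold change of RPKM, so recovery of those changes is overstated there. Beside the 98 and 100 true calls, these 20 were a larger share of calls than the adjusted p threshold is meant to allow. Far fewer genes were changed in the simulation than were called in the data, so neither share carries over to the data. With 22 simulated lists, camera at its preset correlation found 2 of 2 shifted lists of 15 members with 0 false calls. The simulated genes were drawn independently, so this cannot show false calls that arise where list members are correlated. With an estimated correlation it found 0 of 2, so that version had little power for such lists with 4 samples.

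The gene lists, tests and rules for naming genes were set before the data were examined. There were 24 lists, and the 22 with at least 5 tested members were tested with camera from limma, which compares a list's members with all other genes, at a preset inter-gene correlation of 0.01 and with adjustment over the 22 lists. The genes named are TEM1 and its family, the 12 largest significant changes in each direction with the genotypes apart in all samples, up to 4 members of each list with the smallest p, and FT, SOC1, GA3OX1 and GA3OX2. Of the genes these rules pick, 1 is not reported here. Any other gene named was chosen after its values were seen.

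Alternatives set in advance were pseudocounts of 0.1 and 0.25, no filter on low values, a mean RPKM of at least 5, equal sample medians, quantile normalization, limma without trend and with robust variance, each sample left out in turn, the replicate number as a block, an adjusted p under 0.1, a 2-fold limit, and for lists an estimated correlation and fry. The test fry, also from limma, asks whether a list differs from no change, while camera asks whether it differs from other genes, whose median was itself 0.12 higher, so a fry value does not bear on a call of camera. Ranges over the alternatives of a list are of camera alone. Where a sample was left out, its group kept 1 sample, which was assumed to vary like the other group. Such fits had fewer calls in all, so a call lost there with a like fold change is not particular to that gene. A voom test from limma on the recovered reads was added after the data were seen. Python packages pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.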

Results

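Transcript levels were measured by RNA sequencing in whole 10-day-old Arabidopsis plants, in 2 pooled samples of 35S:TEM1 and 2 of wild type. TEM1 (TEMPRANILLO 1) is a transcription factor of the RAV family known as a repressor of flowering. The comparison asks which genes differ when TEM1 is overexpressed, and the series title names salt tolerance, hormones and photoprotection as its subjects. The samples were scaled to between 20.18 and 30.43 M reads (M, units of 1e+06, an estimate from the low values). Samples of the same genotype had a Pearson correlation across genes of 0.991 (35S:TEM1) and 0.990 (WT), and samples of different genotypes of 0.956 to 0.961. Genes are not independent replicates, so these correlations describe the samples only.

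TEM1 (AT1G25560, chromosome 1) had an RPKM of 784 and 827 in 35S:TEM1 replicates 1 and 2, and of 16.3 and 30.3 in WT replicates 1 and 2. The means were 806 ± 30.6 and 23.3 ± 9.90 (SD, n = 2 each), a 34.7-fold difference (log2 fold change 5.12 ± 0.25 SE, limma adjusted p = 0.000247). Reads of the transgene and of the endogenous gene were not told apart. Its relative RAV1 (AT1G13260) fell, from 6.05 and 14.8 in WT to 0.38 and 0.46 in 35S:TEM1 (log2 fold change -2.90 ± 0.35, adjusted p = 0.00314). TEM2 (AT1G68840) had 5.96 and 16.8 in 35S:TEM1 against 12.6 and 20.7 in WT (-0.63, adjusted p = 0.329). Its difference was -1.30 without 35S:TEM1 replicate 2 and past the threshold there and with replicate number as a block, but 0.05 without 35S:TEM1 replicate 1. The remaining member of this list, EDF3, lay under the expression limit. Of the 3 tested members 1 rose and 1 fell, and the counts adjusted over the list alone were the same. With no filter on low values 4 members were tested, with 1 higher and 2 lower. TEM2 was not called there (limma adjusted p = 0.428), so the 2 lower members were RAV1 and EDF3.

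Of 17746 tested genes, 3255 were higher and 1308 lower in 35S:TEM1, together 25.7% of the genes tested. A change of at least 2-fold was seen in 661 higher and 301 lower genes, and of at least 4-fold in 81 and 56. In all of the called genes both 35S:TEM1 samples lay on the same side of both WT samples, which a test of 2 against 2 samples nearly requires. So did 68.0% of all tested genes, where chance gives 33.3% for a single gene. Genes share the same 4 samples and any general shift, so this share is descriptive only. The median of all tested genes was itself 0.12 higher in 35S:TEM1 on the log2 scale. The higher genes made up 71.3% of the calls, against 44.1% (1884 higher, 2388 lower) once every sample was set to the same median and 52.0% (2021 and 1862) with quantile normalization, so the excess of higher genes depends on the scaling. Without 35S:TEM1 replicate 1 there were 1331 higher and 545 lower genes, and without 35S:TEM1 replicate 2 there were 1432 and 597.

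**Figure D1:**
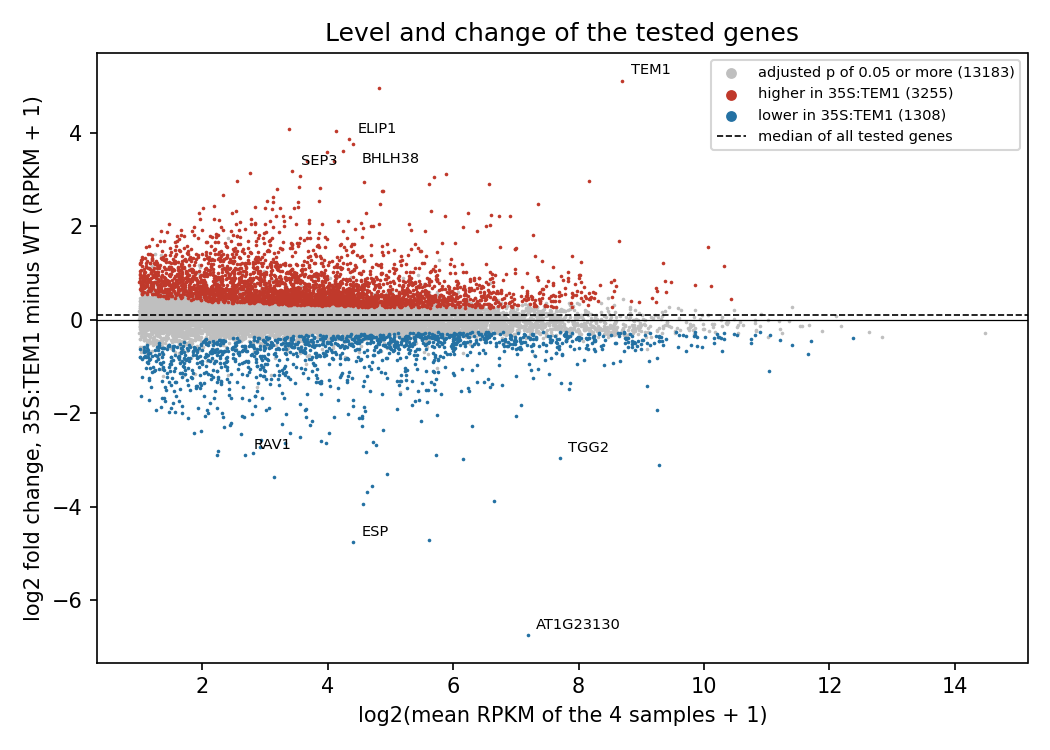
Each point is 1 of the 17746 tested genes, with its log2 mean RPKM + 1 over the 4 samples on the horizontal axis and its log2 fold change between 35S:TEM1 and WT on the vertical axis. The 3255 higher genes are red, the 1308 lower genes blue and the others grey, and the dashed line marks the median of all genes at 0.12, which became -0.03 with equal sample medians.

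The strongest rises were in a mixed set of genes. The non-coding RNA AT1G67105 went from 0.75 ± 0.01 in WT to 53.8 ± 2.24 in 35S:TEM1 (SD, n = 2 each), a log2 fold change of 4.97 ± 0.09 (adjusted p = 3.46e-05). ELIP1, an early light-induced protein of the thylakoid, went from 1.81 ± 1.55 to 36.6 ± 3.3 (3.86 ± 0.36, adjusted p = 0.00135). The bHLH transcription factors BHLH38 and BHLH39, known regulators of iron uptake that lie side by side on chromosome 3, rose by 3.75 ± 0.23 and 3.60 ± 0.34. SEP3, a MADS-box gene of floral organ identity, rose from 1.17 ± 0.44 to 18.5 ± 1.72 (3.18 ± 0.16, adjusted p = 0.000255). LEA7, a late embryogenesis abundant protein, rose by 3.15 ± 0.41, with 16.7 and 6.07 in the 35S:TEM1 samples. The others of the 12 were AT4G01985 of unknown function (4.08), AT2G37870 (4.04) and AT4G33550 (3.40) of the lipid-transfer protein family, AT2G21220 of the SAUR family (3.58), AT3G10950 of a ribosomal protein family (3.40), and AT1G13609, a defensin-like protein (3.13). The gene spans of BHLH38 and LEA7 each overlap a gene on the opposite strand, AT3G56960 and AT1G52695. Whether reads of these genes were counted for BHLH38 and LEA7 is not known.

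The strongest fall was in AT1G23130, of the polyketide cyclase and lipid transport family, from 289 ± 37.1 in WT to 1.74 ± 0.62 in 35S:TEM1 (-6.74 ± 0.17, adjusted p = 4.61e-05). The epithiospecifier protein gene ESP, which steers glucosinolate breakdown towards nitriles, fell from 39.9 ± 4.54 to 0.52 ± 0.09 (-4.74 ± 0.12). TGG2, a myrosinase that cleaves glucosinolates, fell from 368 ± 2.84 to 46.4 ± 1.05 (-2.96 ± 0.07). CER1, an enzyme of cuticular alkane synthesis, fell from 47.2 ± 4.29 to 3.12 ± 0.10 (-3.54 ± 0.10). An abundant transcript of unknown function, AT5G42530, fell from 1111 ± 36.0 to 130 ± 20.8 (-3.09 ± 0.12). The neighbouring genes AT1G67865 and AT1G67860 had log2 fold changes of -4.71 and -3.29. Lectin family members AT3G16530 (-3.93) and AT1G78850 (-3.88), the copper amine oxidase gene AT1G31690 (-3.68), the fatty acid desaturase gene AT1G06100 (-3.36) and the E6-like gene AT2G33850 (-2.98) completed the 12. AT3G16530 overlaps AT3G16525 on the opposite strand.

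**Figure D2:**
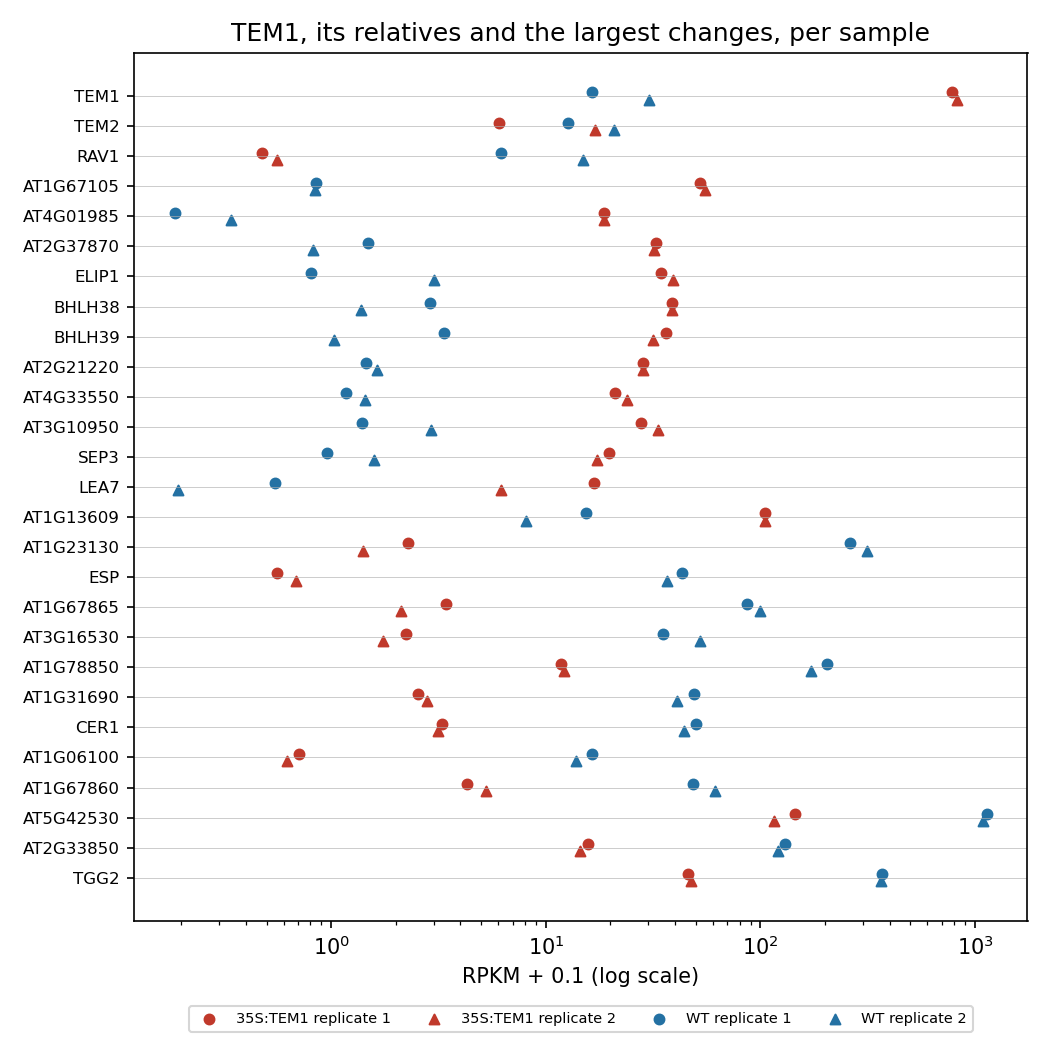
RPKM + 0.1 on a log axis in each of the 4 samples (red 35S:TEM1, blue WT, circles replicate 1, triangles replicate 2) for TEM1, TEM2, RAV1 and the 12 largest rises and 12 largest falls. TEM1 lies at 784 and 827 in 35S:TEM1 against 16.3 and 30.3 in WT, and the genotypes are apart in all genes shown but TEM2.

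Genes of abscisic acid metabolism and response, many of which are induced by drought and salt, were more often higher than lower in 35S:TEM1. Of 28 tested members 14 rose, 3 fell and 11 did not pass the test, and 16 were higher and 3 lower when adjusted over the list alone. COR15A, a chloroplast protein of cold and drought tolerance, rose from 49.0 ± 5.40 to 276 ± 8.28 (2.47 ± 0.10, adjusted p = 0.000162). HAI1, a protein phosphatase of abscisic acid signalling, rose by 2.42 ± 0.12, the transcription factor gene ABF3 by 1.87 ± 0.13 and RD29B by 2.67 ± 0.20. ABF3 overlaps another gene. The list was higher as a set (median 0.46, camera adjusted p = 0.00652), but adjusted p = 0.384 with an estimated correlation, the highest of its alternatives, which started at 0.000457. The set call was also lost with no filter on low values (adjusted p = 0.0667), and without 35S:TEM1 replicate 1 the higher members numbered 9. Root cell markers, with a median of 0.90, were higher and leaf epidermis markers, with a median of -0.25, lower in the same samples.

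In the list of salt, drought and cold response, 7 of 15 tested members rose and 2 fell, and 8 were higher and 2 lower when adjusted over the list alone. The galactinol synthase gene GOLS2 rose from 0.29 ± 0.03 to 5.82 ± 0.50 (2.40 ± 0.13, adjusted p = 0.000307), and RD20, a caleosin, rose by 2.29 ± 0.11. HKT1, a sodium transporter that lowers sodium in the shoot, rose from 1.52 ± 0.08 to 5.10 ± 0.50 (1.27 ± 0.13). In the same samples root cell markers were also higher, with a median of 0.90. ERD5, which breaks down proline, fell from 63.0 ± 2.83 to 21.5 ± 2.39 (-1.51 ± 0.10). As a set the list did not pass (median 0.44, camera adjusted p = 0.104). It passed with equal sample medians (0.0237) and quantile normalization (0.0194), within a range of 0.0194 to 0.526 over the alternatives of camera. The test fry, which compares a list with no change and not with other genes, gave an adjusted p of 0.0202. The 2 lower members became 1 without either 35S:TEM1 replicate and without WT replicate 2.

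Root cell markers were higher in the same samples. All 7 tested members rose, also when adjusted over the list alone, with a median of 0.90 (camera adjusted p = 0.00177, and adjusted p = 0.384 with an estimated correlation, over alternatives from 0.000452). Only 1 of the 7 had a mean RPKM of at least 5, so the main scale understates their change. Their median was 1.55 and 1.39 with pseudocounts of 0.1 and 0.25, and 1.65 with voom. PRP3, a cell wall protein of root hairs, rose by 1.42 ± 0.14, CASP1 of the endodermis by 1.19 ± 0.19, the nitrate transporter gene NRT2.1 by 0.90 ± 0.13 and SCR by 0.72 ± 0.08. With equal sample medians 6 of the 7 were higher, and without 35S:TEM1 replicate 2 there were 4. Leaf epidermis and guard cell markers were lower as a set (median -0.25, camera adjusted p = 0.011, and adjusted p = 0.517 with an estimated correlation, over alternatives from 0.000946). Of its 9 members 2 fell, 0 rose and 7 did not pass, with 3 lower when adjusted over the list alone. PDF1 fell by 0.61 ± 0.10, a call lost without 35S:TEM1 replicate 1 (-0.51), and SPCH by 0.46 ± 0.12, a call lost in each setting without 1 sample (-0.59 to -0.34) and with no filter. The set call was lost without WT replicate 1 (adjusted p = 0.0936), and against no change fry gave 0.32. Of 9 dividing cell markers 0 passed in limma at the main settings, over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. With the replicate block 2 were higher, and with voom 1. Their median was 0.26 (camera adjusted p = 0.33), and without WT replicate 2 the set passed (0.0356, alternatives up to 0.907) and 2 members were higher.

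Among the auxin genes, 6 of 15 rose, 0 fell and 9 did not pass, with the same counts adjusted over the list alone. The conjugating enzymes GH3.5 and GH3.3, both induced by auxin, rose by 2.55 ± 0.12 and 2.40 ± 0.11, IAA29 by 1.24 ± 0.17 and the biosynthesis gene TAA1 by 1.02 ± 0.17. The list was higher as a set (median 0.27, camera adjusted p = 0.0225), with adjusted p = 0.412 with an estimated correlation, over alternatives from 0.0032. Root cell markers, with a median of 0.90, were higher in the same samples. This call was also lost without 35S:TEM1 replicate 2 (adjusted p = 0.0534), with no filter (0.0566) and with a mean RPKM of at least 5 (0.051).

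Cytokinin genes were lower as a set (median -0.44, camera adjusted p = 0.000681, and adjusted p = 0.384 with an estimated correlation, over alternatives from 0.00018), as were leaf epidermis markers (median -0.25). Of 11 members 5 fell, 2 rose and 4 did not pass, and 8 were lower and 2 higher when adjusted over the list alone. The response regulators ARR4 and ARR16 fell by 0.96 ± 0.09 and by 1.24 ± 0.15, and the receptor gene AHK4 fell by 0.67 ± 0.09. CKX4, an enzyme that degrades cytokinin, fell from 5.69 ± 0.02 to 0.76 ± 0.22 (-1.93 ± 0.14, adjusted p = 0.000626). The 2 higher members became 1 without either 35S:TEM1 replicate, and with the replicate number as a block 8 were lower.

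Gibberellin genes did not pass as a set (median 0.37, camera adjusted p = 0.291, alternatives of camera from 0.121 to 0.517), and against no change fry gave 0.0366. GA3OX1, which makes bioactive gibberellin and is a known target of TEM1, fell from 7.14 ± 1.29 to 1.66 ± 0.11 (-1.61 ± 0.14, adjusted p = 0.00126). GA3OX2 lay under the expression limit, with 0.46 and 0.40 against 0.42 and 0.73 in WT. Of 15 tested members 5 rose, among them the biosynthesis gene KAO2 (0.68 ± 0.12) and the inactivating enzyme gene GA2OX6 (0.74 ± 0.19), 1 fell and 9 did not pass. Adjusted over the list alone, 10 were higher and 2 lower. The 5 higher members became 1 without 35S:TEM1 replicate 1, 3 without 35S:TEM1 replicate 2 or WT replicate 1, 2 with equal sample medians or quantile normalization, and 10 with the replicate block. KAO2 lost its call without 35S:TEM1 replicate 1 (0.54), and GA2OX6 lost it without 35S:TEM1 replicate 2 (0.53), without WT replicate 1 (0.62), with both other scalings and with no filter.

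Jasmonate genes went both ways. Of 25 tested members 7 rose, 5 fell and 13 did not pass, and 7 were higher and 6 lower when adjusted over the list alone. VSP2, a vegetative storage protein induced by jasmonate, fell from 41.9 ± 4.47 to 5.04 ± 0.72 (-2.83 ± 0.12), and the repressor gene JAZ9 fell by 1.11 ± 0.08. The biosynthesis genes AOC1 and LOX2 rose by 1.38 ± 0.08 and 0.81 ± 0.08. The median was 0.05, but the mean was -0.13 and camera's direction was lower (adjusted p = 0.273), and the median turned to -0.10 with equal sample medians and -0.07 with quantile normalization. Higher members numbered 3 without 35S:TEM1 replicate 1 and 4 without 35S:TEM1 replicate 2, where 3 were lower, and lower members numbered 8 without WT replicate 1.

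Among ethylene genes 3 of 16 fell, 2 rose and 11 did not pass, with 3 and 3 adjusted over the list alone. The ethylene-forming oxidase gene ACO4 fell by 1.38 ± 0.15, and the transcription factor gene ORA59 fell by 1.28 ± 0.21. EBF1 rose by 0.41 ± 0.07, a call lost without either 35S:TEM1 replicate (0.42 and 0.41). The set did not pass (median -0.12, camera adjusted p = 0.137), but did with no filter (0.0451), without 35S:TEM1 replicate 2 (0.0332), without WT replicate 1 (0.0227) and with the replicate block (0.0358), with alternatives of camera up to 0.505. The higher members became 0 without either 35S:TEM1 replicate and 1 without WT replicate 1, where 5 were lower. The median was 0.14 without 35S:TEM1 replicate 1 and 0.11 without WT replicate 2.

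Of 18 tested genes of salicylic acid and pathogen defence 2 rose (PAD4, 0.47, and EDS5, 0.38), 1 fell (WRKY70, -1.22 ± 0.34) and 15 did not pass, and adjusted over the list alone 0 passed, against 5 with an unadjusted p under 0.05. No call held without 35S:TEM1 replicate 1, where PAD4 had 0.36, EDS5 0.38 and WRKY70 -0.84, and without 35S:TEM1 replicate 2 WRKY70 alone passed. WRKY70 had -0.79 and did not pass without WT replicate 2, nor did it without trend (adjusted p = 0.0601) or with robust variance (0.124). With no filter 0 members passed, the adjusted p being 0.0686 for PAD4, 0.0823 for EDS5 and 0.0884 for WRKY70. The set did not pass (median -0.02, camera adjusted p = 0.33). It passed as lower without WT replicate 1 (adjusted p = 0.0185, alternatives up to 0.971), where 6 members were lower and 1 higher, and its direction turned to higher without WT replicate 2. EDS5 and PAD4 did not pass with equal sample medians, quantile normalization or without WT replicate 2, nor EDS5 without WT replicate 1. Of 9 brassinosteroid genes 2 rose, 1 fell and 6 did not pass, also when adjusted over the list alone (median 0.23, camera adjusted p = 0.33). ROT3, a biosynthesis enzyme, rose by 0.93 ± 0.11. The receptor gene BRI1 (0.51 ± 0.09) lost its call without either 35S:TEM1 replicate (0.53 and 0.48), and BR6OX2 (-0.46 ± 0.11) lost it in all 4 such settings, with values from -0.56 to -0.37, and with no filter. Without WT replicate 1 there were 4 higher members.

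Of 14 tested flowering-time regulators 4 rose, 2 fell and 8 did not pass, and 5 were higher and 2 lower when adjusted over the list alone. FT, the mobile flowering signal whose gene TEM1 is known to repress, had 9.21 and 7.40 in 35S:TEM1 against 4.00 and 4.80 in WT (0.78 ± 0.14, adjusted p = 0.0113). This call was lost without 35S:TEM1 replicate 1, where the log2 fold change was 0.64. The floral activators AGL24 and SPL4 rose by 1.23 ± 0.20 and 1.02 ± 0.12, and the repressor gene FLC fell by 0.85 ± 0.18, which was lost without 35S:TEM1 replicate 1 (-0.65) and without WT replicate 1 (-0.74). SOC1 had 12 ± 0.28 and 12.8 ± 1.42 (-0.09, adjusted p = 0.558). The list did not pass as a set (median 0.21, camera adjusted p = 0.659). Without 35S:TEM1 replicate 1 there were 2 higher and 0 lower members, and the lower members became 1 without either WT sample. FLC and SPL4 overlap other genes.

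Clock genes numbered 16, of which 3 rose, 1 fell and 12 did not pass, with 4 higher and 1 lower adjusted over the list alone (median 0.27, camera adjusted p = 0.216, alternatives of camera from 0.0613 to 0.517, and fry 0.0419 against no change). At this single time of day, RVE8 rose by 0.64 ± 0.09 and the evening complex gene LUX fell by 0.82 ± 0.13. CCA1 rose by 0.82 ± 0.17, and LNK2 by 0.43 ± 0.12. Both of these lost their calls without either 35S:TEM1 replicate, which left 1 higher member, LNK2 did so without each WT replicate, with both other scalings and with no filter, and the replicate block gave 6.

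Photoprotection genes diverged. The early light-induced protein genes ELIP1 and ELIP2 rose by 3.86 ± 0.36 and 2.83 ± 0.34, and VTE4, which makes alpha-tocopherol, fell from 18.6 ± 2.54 to 4.18 ± 0.66 (-1.92 ± 0.14, adjusted p = 0.000657). LUT2 of lutein synthesis rose by 0.47 ± 0.08, a call lost without 35S:TEM1 replicate 1 (0.42). Of 21 members 3 rose, 3 fell and 15 did not pass, and 6 were higher and 5 lower when adjusted over the list alone. The median was -0.01 and camera's direction lower (adjusted p = 0.332), while the mean was 0.23 and fry's direction higher, and the median turned slightly positive with quantile normalization. With equal sample medians 7 were lower, and the lower members became 1 without either 35S:TEM1 sample. VTE4 and LUT2 each overlap a neighbour, LUT2 on the same strand.

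Of 18 light-harvesting antenna genes 6 rose, 2 fell and 10 did not pass, with the same counts adjusted over the list alone. The 4 members with the smallest p were LHCB2.2 (1.49 ± 0.23), LHCB2.1 (1.0 ± 0.18), LHCB2.3 (0.90 ± 0.20, lost with no filter and without either 35S:TEM1 replicate, 0.86 and 0.95) and LHCB1.2 (0.76 ± 0.11). Copies of these genes may share reads, which was not checked. The set did not pass (median 0.07, mean 0.29, camera direction lower, adjusted p = 0.904). The median turned to -0.08 with equal sample medians, and with quantile normalization the set passed as higher (adjusted p = 0.018, alternatives up to 0.992) with 0 lower members. Without 35S:TEM1 replicate 1, and likewise without 35S:TEM1 replicate 2, there were 3 higher and 0 lower members, and without WT replicate 2 there were 6 lower.

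Among genes of reactive oxygen scavenging 4 of 16 rose, 2 fell and 10 did not pass, also when adjusted over the list alone. The dehydroascorbate reductase gene DHAR1 rose by 0.89 ± 0.07 and the copper/zinc superoxide dismutase genes CSD1 and CSD2 rose by 0.69 ± 0.07 and 0.49 ± 0.11, while the iron superoxide dismutase gene FSD1 fell from 350 ± 32.3 to 194 ± 22.5 (-0.85 ± 0.11, adjusted p = 0.00394). CSD2 lost its call with equal sample medians (0.34) and without either 35S:TEM1 replicate (0.57 and 0.40). The median was -0.03 and the mean 0.03, with camera's direction lower (adjusted p = 0.382). There were 2 higher and 4 lower members with equal sample medians, and leaving out either 35S:TEM1 sample gave 2 higher and 1 lower.

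Flavonoid and anthocyanin genes were lower as a set (median -0.23, camera adjusted p = 6.92e-05). With an estimated correlation it had adjusted p = 0.517, over alternatives from 3.32e-06, and against no change fry gave 0.108. Leaf epidermis markers, with a median of -0.25, were lower in the same samples. Of 19 tested members 8 fell, 0 rose and 11 did not pass, and 9 were lower and 1 higher when adjusted over the list alone. The late anthocyanin genes DFR, LDOX and UF3GT fell by 1.58 ± 0.10, by 1.51 ± 0.11 and by 1.4 ± 0.12, and PAL2, at the entry of the pathway, fell by 0.73 ± 0.08. The chalcone synthase gene TT4, named after its value was seen, had 328 ± 31.5 and 324 ± 22.0 (0.01, adjusted p = 0.931). Without 35S:TEM1 replicate 2 there were 5 lower members. F3H lay under the expression limit and overlaps a listed gene on the opposite strand.

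Trichome initiation regulators were lower as a set (median -0.57, camera adjusted p = 5.07e-05, and adjusted p = 0.384 with an estimated correlation, over alternatives from 5.03e-06). Of 10 tested members 5 fell, 0 rose and 5 did not pass, and 6 were lower when adjusted over the list alone. GIS fell from 5.67 ± 1.42 to 0.58 ± 0.15 (-2.06 ± 0.18), GL2 from 6.72 ± 0.002 to 2.06 ± 0.01 (-1.34 ± 0.11) and GL1 from 3.81 ± 0.32 to 0.97 ± 0.25 (-1.29 ± 0.15), all activators of trichome development. ETC1, a repressor of it, fell by 0.64 ± 0.15, a call lost in each setting without 1 sample, with values from -0.76 to -0.52. Without 35S:TEM1 replicate 1, and likewise without 35S:TEM1 replicate 2, there were 3 lower members. GL2 and ETC1 overlap other genes. Leaf epidermis markers had a median of -0.25 in the same samples and root cell markers of 0.90.

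Glucosinolate genes were also lower as a set (median -0.13, camera adjusted p = 0.0225, and adjusted p = 0.412 with an estimated correlation, over alternatives from 0.0073). Of 14 members 6 fell, 2 rose and 6 did not pass, also when adjusted over the list alone. The myrosinase genes TGG1 and TGG2 fell by 1.92 ± 0.13 and by 2.96 ± 0.07, and CYP79F1 of the methionine-derived branch fell by 0.86 ± 0.11. CYP83A1 of the same branch rose by 0.77 ± 0.10. Leaf epidermis markers had a median of -0.25 in these samples. The set call was lost without WT replicate 2 (adjusted p = 0.0863), with equal sample medians (0.0954), with quantile normalization (0.125) and with a mean RPKM of at least 5 (0.0887).

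Of 7 tested senescence and sugar starvation genes 2 rose and 2 fell, also when adjusted over the list alone. The sugar starvation gene DIN10 fell from 131 ± 49.0 to 25.4 ± 0.97 (-2.27 ± 0.23), and ASN1, asparagine synthetase, fell by 0.93 ± 0.24. The ASN1 call was lost with no filter, without 35S:TEM1 replicate 2 (-0.66) and without WT replicate 1 (-0.67). NYE1 (0.47) and DIN2 (1.12) did not pass with no filter, equal sample medians, quantile normalization or without 35S:TEM1 replicate 1 (0.35 and 0.66) or WT replicate 2 (0.39 and 1.17), nor NYE1 without 35S:TEM1 replicate 2 (0.59) or DIN2 without WT replicate 1 (1.07). The median was 0.04, the mean -0.32 and camera's direction lower (adjusted p = 0.33), and the median turned to -0.11 with equal sample medians. Of 3 tested heat shock genes HSP70 rose by 0.95 ± 0.19, a call lost without 35S:TEM1 replicate 2 (0.68), and 2 did not pass, also when adjusted over the list alone.

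The reference genes used for normalization in other assays served as a control. GAPC2 (0.45 ± 0.07) and SAND (0.38 ± 0.08) were higher among 9 members, 0 were lower, and 4 were higher when adjusted over the list alone. The set did not differ from other genes by the test (median 0.07, camera adjusted p = 0.904), and the median was -0.08 with equal sample medians and -0.04 with quantile normalization. With equal sample medians 1 member was higher and 1 lower, and SAND did not pass there or with quantile normalization. Leaving out either 35S:TEM1 sample left 0 higher members, GAPC2 then having 0.48 and 0.42 and SAND 0.36 and 0.40, and without WT replicate 2 there was 1 lower.

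**Figure D3:**
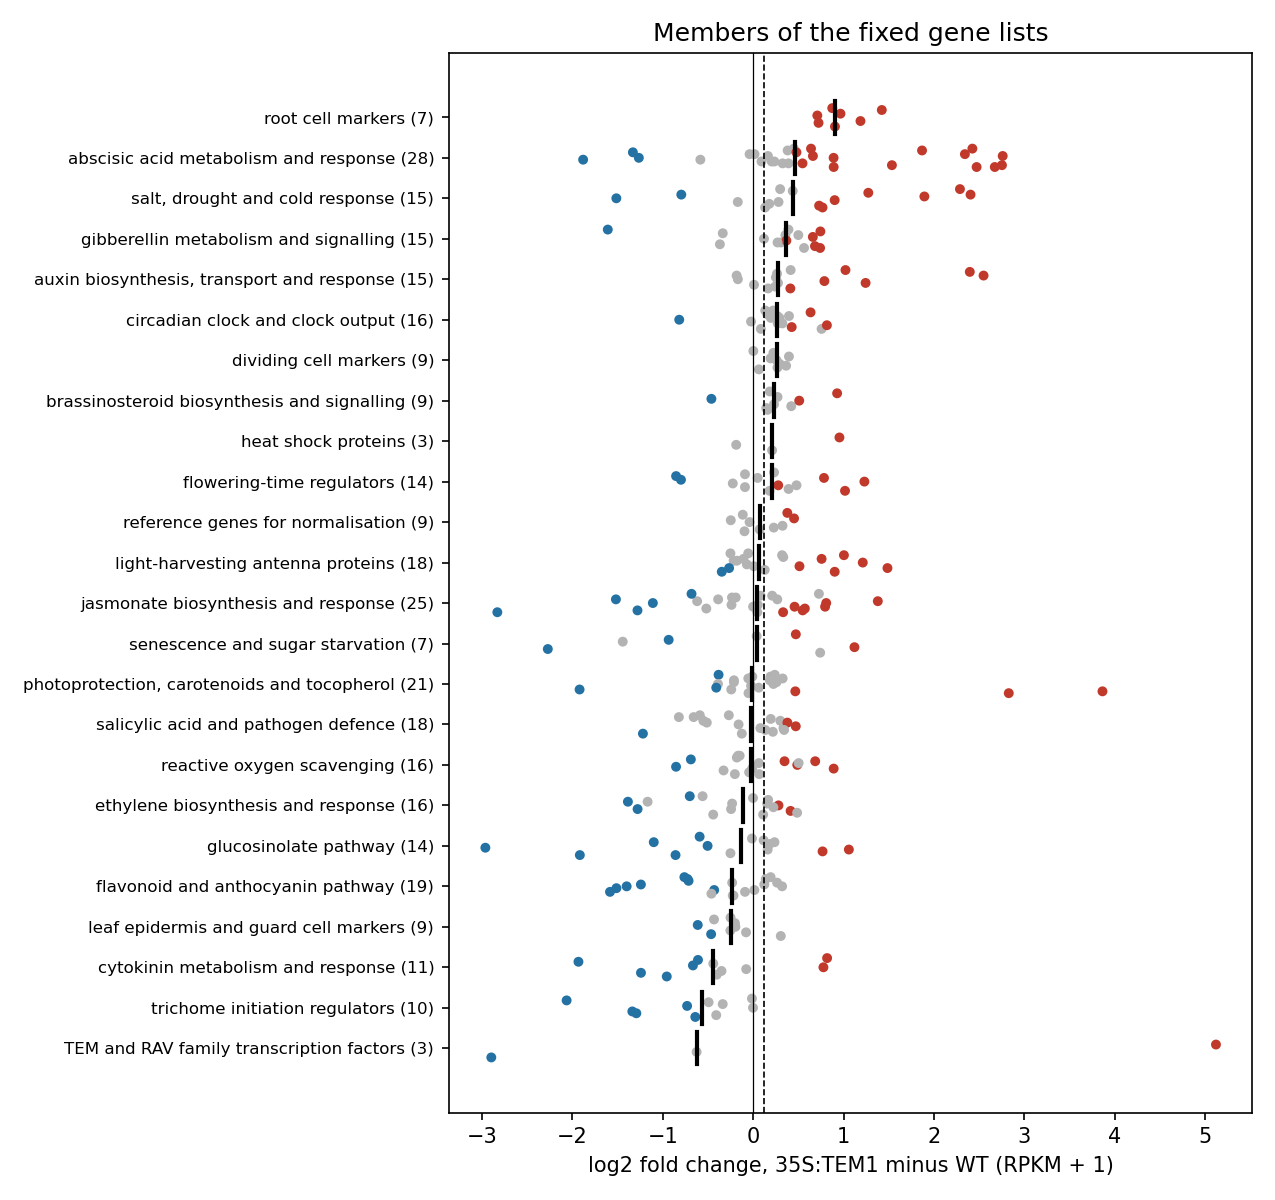
Log2 fold change between 35S:TEM1 and WT of each tested member of the 24 lists, with the number tested in brackets, red for higher, blue for lower and grey for members that did not pass. Black bars are list medians, from 0.90 for root cell markers to -0.57 for trichome regulators among lists of at least 5 members, and the dashed line is the median of all genes at 0.12. With equal sample medians the jasmonate, antenna, senescence and reference medians turned negative.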

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

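The voom test on recovered reads was chosen only after the data were seen. TEM1 stayed past the threshold in each alternative, with log2 fold changes of 4.69 to 5.55. No gene called at the main settings was called with the opposite sign in any alternative, and equal sample medians shared 3192 of the 4563 calls, voom 4406. The higher genes numbered 1884 with equal sample medians, 2021 with quantile normalization, 661 with a 2-fold limit and 1331 to 2955 without 1 sample. Lower genes numbered 2388 with equal sample medians, 301 with a 2-fold limit and 545 to 1417 without 1 sample. The smaller counts under the limit follow from its construction, and those under the scalings from the median of all genes, which they took from 0.12 to -0.03 and -0.01. The fits without a 35S:TEM1 replicate had fewer calls than those without a WT replicate. Their residual spread came from the WT pair alone, which had an SD of difference of 0.254, against 0.234 for the 35S:TEM1 pair. A call lost there therefore does not show that a 35S:TEM1 sample was unstable. Whether this spread is the whole cause was not tested. Of 22 lists 8 passed at the main settings. With a mean RPKM of at least 5 only 19 lists kept enough members to be tested, of which 4 passed, and of the 8 calls 2 were not past and 2 (trichome and root) were untested. None, 0 of 22, passed with an estimated correlation, which found 0 of 2 simulated lists. That correlation was 0.56 for flavonoid and 0.35 for leaf epidermis, and between -0.06 and 0.05 for the other lists that had passed. The simulated genes were independent, so the simulation cannot speak for the preset of 0.01 where members are correlated. With an estimated correlation the adjusted p was 0.384 for abscisic acid, cytokinin, trichome and root, 0.412 for auxin and glucosinolate and 0.517 for flavonoid and leaf epidermis. With no filter it was 0.0667 for abscisic acid, 0.0566 for auxin and 0.0451 for ethylene, and with a mean RPKM of at least 5 it was 0.051 for auxin and 0.0887 for glucosinolate. Equal sample medians gave 0.0954 for glucosinolate and 0.0237 for salt, drought and cold, and quantile normalization 0.125 and 0.0194 for these and 0.018 for the antenna list, which turned from lower to higher. Against no change, a different question from the comparison with other genes, fry gave 0.108 for flavonoid, 0.32 for leaf epidermis, 0.0366 for gibberellin, 0.0202 for salt, drought and cold and 0.0419 for clock genes. With the replicate block it was 0.0358 for ethylene. Without 1 sample it ran from 0.0032 to 0.0534 for auxin, 0.0073 to 0.0863 for glucosinolate, 0.000946 to 0.0936 for leaf epidermis, 0.0227 to 0.271 for ethylene, 0.0185 to 0.971 for salicylic acid and 0.0356 to 0.907 for dividing cells. Beyond the estimated correlation, the limit on RPKM and the question of fry, the cause of these changes was not tested.

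The lower of the correlations within a genotype was 0.9865 and 0.9879 with pseudocounts of 0.1 and 0.25, 0.994 with no filter, 0.9885 with a mean RPKM of at least 5 and 0.9872 with voom, and the cause was not tested. Among 116 genes named by rule besides TEM1, calls lost numbered 22 and 17 without 35S:TEM1 replicates 1 and 2, 9 without each WT replicate, 11 with no filter, 8 with equal sample medians and 7 with quantile normalization.

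With the replicate number as a block (replicate block), 4321 genes were higher and 1801 lower, all 4563 calls among them, and TEM1 had 5.12. The differences between replicates 1 and 2 correlated at 0.318 across genes between the genotypes. With only 2 pairs and no label that links equal numbers, the numbers were not taken to pair the samples. At 20.18 to 30.43 M reads, 3 reads in a 1 kb gene are an RPKM of 0.099 to 0.149, so values near it are limited by depth.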

Other observations

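Genes of the iron deficiency response, a list chosen after 2 of its members had appeared among the largest rises, were mostly higher in 35S:TEM1. Of 18 tested members 15 rose and 1 fell, with a median log2 fold change of 1.44 (camera p = 2.15e-07, unadjusted, and p = 0.113 with an estimated correlation). Without those 2, BHLH38 and BHLH39, 13 of 16 rose and 1 fell, with a median of 1.38 (camera p = 3.27e-06, and p = 0.116 with an estimated correlation), and the choice of the list still followed from the data. BHLH38, BHLH39 and BHLH100 rose by 3.75 ± 0.23, 3.60 ± 0.34 and 2.95 ± 0.38 (SE). The genes of the signalling peptides IMA2 and IMA3 went from 21.4 ± 0.93 to 167 ± 0.05 and from 19.5 ± 2.01 to 95.0 ± 6.20 (SD, n = 2 each). The ferric reductase genes FRO3 and FRO2 rose by 2.07 ± 0.15 and 1.32 ± 0.11, the transporter genes OPT3 and IRT1 by 1.53 ± 0.09 and 1.14 ± 0.13, and the regulators BTS and PYE by 1.47 ± 0.12 and 1.41 ± 0.09. FIT1, the main activator of iron uptake in roots, had 2.73 ± 0.11 and 2.52 ± 0.52 (0.09, limma adjusted p = 0.67), and NAS4 fell by 1.1 ± 0.11. The ferritin genes FER3 and FER4, which store iron, fell by 0.48 ± 0.11 and by 0.65 ± 0.11, and FER1 had -0.56 (adjusted p = 0.0568). In the list of iron storage and sufficiency as a whole, 2 of 7 rose and 2 fell (camera p = 0.339, and p = 0.736 with an estimated correlation). Root cell markers had a median of 0.90 in the same samples. Their median was 1.55 with a pseudocount of 0.1, a setting in which the iron lists were not tested.

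Copper-responsive genes, also chosen afterwards, had 5 of 9 tested members higher and 1 lower (median 0.48, camera p = 0.013, and p = 0.123 with an estimated correlation). The list was not divided by the direction in which its members respond to copper. The counts and the set test therefore do not show whether the plants had more or less copper. Without FSD1, CSD1 and CSD2, which are also in a fixed list, 3 of 6 were higher and 0 lower (median 0.38, camera p = 0.00455, and p = 0.101 with an estimated correlation). Root cell markers had a median of 0.90 in the same samples. The copper transporter gene COPT2 rose from 9.45 ± 0.01 to 41.2 ± 3.76 and YSL2 from 6.35 ± 0.40 to 20.6 ± 0.67 (SD, n = 2 each). CSD1 rose by 0.69 ± 0.07 while FSD1, the iron enzyme of the same reaction, fell by 0.85 ± 0.11 (SE). Organelle-encoded transcripts made up 0.064% and 0.1% of the summed RPKM for the chloroplast in 35S:TEM1 and 0.05% and 0.057% in WT, and 0.019%, 0.032%, 0.009% and 0.013% for mitochondria.

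The tests on the most abundant transcripts, on the split of the samples, on the spread of root transcripts and on neighbouring genes were chosen only after the result was seen. More genes were higher than lower (71.3% of calls). A smaller share of reads in the 20 most abundant transcripts of 35S:TEM1 (10.48% and 11.19%, against 12.37% and 12.69% in WT) is not the whole cause, because the median difference was still 0.0917 after scaling to the reads outside these. Nor is depth, since replicate 2, where 35S:TEM1 was deeper, also had a median difference of 0.0973. A change in composition over more transcripts may contribute and cannot be told apart from a true general rise, because setting equal medians moves the split towards balance (44.1% higher) by its construction, a reason for setting that test aside that was given after its value was seen. Of the 3 splits of the 4 samples only 1, the real one, had as many as 4563 calls in limma, the highest of the others had 0 (182 and 29 genes at an unadjusted p under 0.05), and 3 splits are too few for a share under 0.05. The other splits also put both genotypes in each group. The difference between genotypes then enters the spread, so few calls follow by construction and no conclusion is drawn.

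Root cell markers were higher. A general shift of scale as the whole cause is argued against by its size. The smallest rise of the 7 was 0.71, while the median of all tested genes was 0.12 higher. With equal sample medians 6 of 7 were still higher, which follows largely from that gap. A larger share of root in the 35S:TEM1 pools may contribute, as a separate list of abundant root transcripts, written before its values were seen, had a median of 1.04, with 9 of 14 higher and 0 lower (camera p = 0.000121, and p = 0.0679 with an estimated correlation). Whether it is the whole cause cannot be told. The fold changes of those transcripts had an SD of 0.61, 3.96 times their median SE, with DR4 at -0.05 and TIP2.2 at 0.21 against TIP2.3 at 1.68, but a larger root share moves them alike only if all have the same ratio of root to shoot levels, which was not measured, a reason for setting that test aside that was given after its value was seen. Levels of the most abundant, PYK10, were 360 ± 6.98 and 238 ± 41.7 (SD, n = 2 each), and a change of root genes by TEM1 itself stays open and untested.

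Neighbouring genes on chromosome 1 stood among the 119 genes that fell by at least 1.5 on the log2 scale. VTE4, XTH17, GLC, AT1G65490 and HEXO3 lay within 50 consecutive tested genes, near FT, and 0.0347 of 10000 random placements had as many. Tandem families are argued against as the cause, since the share was 0.022 with runs counted once. A difference in the genome between the lines may contribute, but the grouping depends on the limits: over 9 combinations of fold limit and window the share ran from 0.008 to 0.864, and 2 were under 0.05. The requirement that most combinations show it was set after these values were seen, and no genotype data were used here, so this stays open.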
